A study of Caenorhabditis elegans with 3 samples.

How the data were processed

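RNA of adult Caenorhabditis elegans hermaphrodites, read from the labels as carrying embryos, was hybridised against a mixed wild-type reference RNA on 2-colour arrays. There were 3 arrays, 1 for each of 3 worm preps (preps 1 to 3), and they form 1 group. The labels put the reference in channel 1 and the adult RNA in channel 2 and do not give the dyes. The labels say "adult w/ emb 2": "w/ emb" was read as carrying embryos, and the number 2 after it and the code TP11 were left unread. Nothing in the labels says whether the preps were separate cultures, so the p-values measure the spread between these samples, which may be technical. The reference was taken as 1 comparator, and whether it was 1 pool for all arrays is not known here. Any difference between its samples cannot be separated from that between the preps. Each array carries its own array label, which ends in what may be a date. With 1 array per prep a batch cannot be told apart from the prep, and none was fitted.

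The authors deposited a table of log ratios for 20000 probes, with 1 column per array, and all of its columns were used. Its log base, normalization, filtering and direction are not given in the sources used here. The base was settled from the values: 100% of the deposited values correspond, as log2 ratios, to a ratio that is a multiple of 0.001 within 0.00005 (ratios under 3), against 10.7% when read as natural logs and 8.89% when read as base 10. The deposited log2 ratios had medians of 0.019, 0.072 and −0.0087 on preps 1, 2 and 3, and how the authors centred them stays unknown. Positive was taken as channel 2 over channel 1, that is adult RNA over reference. This direction follows the order of the channels and is likely, not settled. Spot intensities were not used here, so dim spots could not be filtered, intensity-dependent dye effects could not be corrected, and the number of arrays sets the precision. Values were present for 19888, 19821 and 19798 probes on preps 1, 2 and 3. For 19710 probes they were present on all 3 arrays, and 53 probes had none.

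Probe genes came from the platform annotation. Of the 20000 probes, 15655 had 1 gene, 198 had several and were named for none of them, and 4147 are unnamed here. Symbols were updated through a RefSeq gene table of the assembly WBcel235, by gene ID for 15569 probes and by accession for 7, and 79 probes kept the platform symbol. The probes with 1 gene covered 15168 genes. The genome build behind the probe design is not given in the sources used here, and no coordinates are reported. Probes of gene families with near-identical members, such as the major sperm proteins, histones and some collagens, can bind more than the named member, so values of single members of these families are uncertain.

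Each array was centred on its median. A model with an intercept only was fitted to the log2 ratios of the 19710 probes with limma (lmFit and eBayes, no trend, not robust), and the mean ratio was tested against 0 with its two-sided moderated test. P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. The fit had 2 residual and 8.957 prior degrees of freedom, and the median standard error of a mean log2 ratio was 0.182. A gene with several probes is given as the mean of its probes with the largest of their adjusted p-values, and counts as past the threshold when at least 1 of its probes passes. No gene of the lists had probes past the threshold in both directions. Means are given with the SD over the 3 preps.

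Before the data were examined, 26 gene lists were fixed, some by gene names and some by family symbols. Each list with at least 5 measured genes (25 lists) was compared with all other probes by limma's camera, two-sided, with the inter-gene correlation preset to 0.01 and Benjamini-Hochberg adjustment over the lists. The camera test with a correlation estimated from the residuals, and limma's fry, stand beside it. With 3 arrays that correlation is estimated from 2 residual degrees of freedom. The camera test then also has 2 degrees of freedom, so few lists could pass it whatever their correlation. For the moulting and apical matrix list, with an estimated correlation of 0.034, the unadjusted p of camera went from 2.4e-07 to 0.070. A call lost in this form of the test therefore does not by itself show that correlation between genes undid it. Among the lists that passed with the preset, this list had the lowest estimated correlation. The others ran up to 0.738 for maternal RNA regulators and 0.764 for the proteasome, with 0.393 for the cuticle collagens. Where the true correlation is far above 0.01, the p-values with the preset are too small. The 2 reasons for a lost call were not separated. With the preset correlation 14 lists passed. With the estimated correlation 0 of the 25 lists passed, and 0 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance in a single direction, 0 lists passed after adjustment (lowest adjusted p = 0.083) and 12 had an unadjusted p under 0.05. By fry's mixed test for change in either direction 21 lists passed. Neither fry test compares a list with other genes.

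The genes named in the text follow a rule fixed at the same time. Among probes past the threshold with the same sign on all 3 arrays and exactly 1 gene with a symbol other than its sequence name, the 12 largest positive and the 12 largest negative mean ratios are named, with at most 2 genes per family. From each list the 2 highest and 2 lowest members may be named, and the yolk protein list is given in full. Where a count of list members is 5 or fewer, members outside this rule are named too (such as cpg-3, hsp-70, spe-12 and rpl-38), which were chosen after their values were seen. Splits of the heat shock and major sperm protein lists by gene symbol, tested by camera with adjustment over the 4 parts, were added after the data were seen. Genes named in the closing observations from families and numbered pairs fall outside this rule and were chosen after their values were seen.

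The fit was tested on simulated data for 19710 probes, 200 of them changed, at 3 arrays. It recovered 0% of probes changed by 0.5 on the log2 scale, 6% of those changed by 1, 80% at 2 and 96% at 3, and it called 1 unchanged probe. Fewer probes were changed there than were called in the data, which makes the adjusted threshold stricter in the simulation. The simulation also took each probe's SD over the 3 arrays as its true spread. That SD is itself uncertain, so the simulated spreads varied more between probes than the true ones would. The recovered shares are therefore not the power of the fit on the real data. The alternatives were other centrings and scalings between arrays, probes on at least 2 arrays (with limma's cameraPR for the lists, because of missing values), a robust and trended eBayes, limma's treat against a log2 ratio of 0.5, leaving out each prep, limiting ratios to a log2 of 4 in size, and 1 row per gene. Trimmed mean centring, the robust and trended eBayes, treat and the limit on ratios were run for the probe counts alone, not for lists or single genes. After seeing the data, the removal of a running median over 101 consecutive probe IDs and the addition of probes with several genes to the family lists were added. The work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.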

Results

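The series compared the mRNA of adult C. elegans hermaphrodites, read from the labels as carrying embryos, with a mixed wild-type reference RNA. The comparison asks which transcripts were more or less abundant in these adults than in the mixture. Log2 ratios of 3 worm preps were measured, each on its own 2-colour array. Over 19710 probes, which are not independent replicates, the ratios correlated with a Pearson r of 0.776 (Spearman rho 0.694) between preps 1 and 2, 0.799 (0.740) between preps 1 and 3, and 0.829 (0.752) between preps 2 and 3. The spread of the ratios differed, with a robust SD of 0.773 on prep 1, 0.484 on prep 2 and 0.370 on prep 3.

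A positive ratio is read as more RNA in the adults than in the reference, from the order of the channels in the labels. The labels do not name the dyes, so this direction is likely and not settled. The markers fixed for it were yolk protein and eggshell genes. Of the 3 yolk protein genes measured, vit-2 had a log2 ratio of 1.00 ± 0.35 (SD, n = 3) with an adjusted p of 0.0023 in limma. The ratios of vit-6 (0.22 ± 0.15) and vit-5 (−0.15 ± 0.27) did not differ from 0, with adjusted p-values of 0.381 and 0.578. The yolk list averaged 0.36 ± 0.12 and was too small for a list test, and vit-2 alone passed the threshold adjusted over the list alone too. Of the 14 eggshell and egg activation genes, 11 were positive past the threshold and 3 did not pass. All "higher" and "lower" statements rest on this reading.

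Of the 19710 probes, 6302 (32.0%) differed from a ratio of 1 in limma, 3116 higher and 3186 lower in the adults. At a ratio of at least 2-fold there were 1102 higher and 1326 lower probes. Centring each array on its median draws the split of higher and lower probes toward even. Without centring 3356 were higher and 3065 lower. Among the 6302, 6283 had the same sign on all 3 arrays. Over all tested probes 61.0% had the same sign on all 3. Without prep 1, the array with the widest spread, 710 probes were higher by at least 2-fold. Counts of list members below are to be read beside the 32.0% of all probes past the threshold, 49.4% of them higher. A count near that share is no trait of its list.

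Of the 12 named genes with the highest ratios, the infection response gene irg-5 was 17.9-fold higher (log2 4.16 ± 1.48, SD, n = 3), with a lowest array value of 2.45 on prep 3, and irg-8 had a log2 ratio of 2.49 ± 0.59. The genes pud-2.1 (3.26 ± 0.76) and pud-4 (2.35 ± 1.08), named for proteins that are abundant in daf-2 mutants, were higher. So were the cytochrome P450 gene cyp-35C1 (3.12 ± 0.98), the UDP-glucuronosyltransferase gene ugt-22 (2.92 ± 0.37) and hrg-7 (2.47 ± 0.27), a heme-responsive gene that encodes an aspartic protease. The yolk receptor gene rme-2 reached 2.45 ± 0.74, the RNA-binding Pumilio-family gene puf-6 2.41 ± 0.50, and the eggshell genes cbd-1 and cpg-1 2.38 ± 0.48 and 2.33 ± 0.66. A single collagen gene, col-101 (2.65 ± 0.45), was among them. The adjusted p-values of these 12 genes in limma ran from 5.5e-06 for ugt-22 to 0.00032 for pud-4.

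Of the 12 named genes with the lowest ratios, the alcohol dehydrogenase gene adh-1 was 39.2-fold lower (log2 −5.29 ± 0.67), followed by the acyl-CoA synthetase gene acs-2 at −5.19 ± 0.90 and the C-type lectin gene clec-60 at −5.0 ± 0.65. The collagen genes rol-8 (−4.73 ± 0.43), col-36 (−4.59 ± 0.31), col-158 (−4.14 ± 1.09) and rol-6 (−3.56 ± 1.34) were lower, as were the small heat shock protein gene hsp-12.6 (−4.41 ± 0.45) and the fatty acid desaturase gene fat-3 (−4.26 ± 0.32). The gene scl-2 stood at −3.97 ± 0.76, the fatty acid and retinol binding protein gene far-7 at −3.77 ± 0.46, and the neuropeptide-like gene nlp-80 at −3.47 ± 0.23. Adjusted p-values in limma for these 12 genes lay between 3.7e-07 for col-36 and 7.3e-05 for rol-6.

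**Figure D1:**
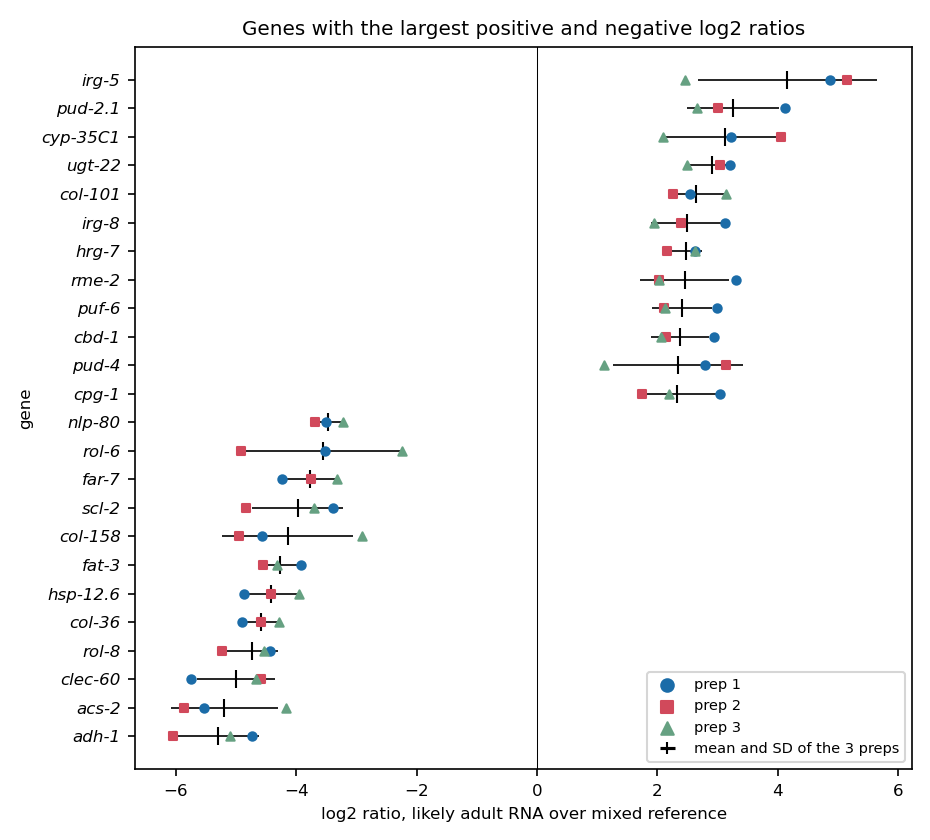
Log2 ratios (x axis, likely adult RNA over mixed reference) of the 12 genes with the largest positive and the 12 with the largest negative means among the named genes (y axis); points are the 3 preps, ticks and bars their mean and SD. All 3 points of each gene lie on the same side of 0, as the naming rule required, and irg-5 (SD 1.48) and rol-6 (SD 1.34) have the widest bars.

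The lists of maternal RNA regulators, eggshell genes and germ granule genes were higher in camera with the preset correlation (adjusted p = 2.8e-18, 2.2e-07 and 5.3e-15). None of these calls held in camera with an estimated correlation (adjusted p = 0.58 for each list). That form of the test has 2 degrees of freedom, and few lists could pass it. Of 34 genes measured in the maternal RNA regulator list, 31 were higher, and the list averaged 1.41 ± 0.47. Besides RNA-binding and translation regulators this list holds genes with other functions, such as the yolk receptor gene rme-2. Beside rme-2 and puf-6 at its top, puf-8 (0.29 ± 0.11), etr-1 (0.05 ± 0.04) and puf-9 (0.04 ± 0.14) did not pass the test. Of the 14 eggshell and egg activation genes, 11 were higher (mean 1.22 ± 0.35), with cbd-1 and cpg-1 highest. Its other members cpg-2 (0.04 ± 0.02), egg-1 (−0.31 ± 0.07) and cpg-3 (0.53 ± 0.33) did not pass. The adjusted p of cpg-3 was 0.050, against 0.036 without centring, 0.049 and 0.029 after scaling and quantile normalization, and 0.035 without prep 2. Germ granule and germline chromatin genes were higher for 24 of 29 members (mean 1.23 ± 0.23), led by the Vasa-related helicase genes glh-2 (2.31 ± 0.35) and glh-1 (2.31 ± 0.57), while the Polycomb-type genes mes-3 (0.29 ± 0.14) and mes-2 (0.11 ± 0.29), znfx-1 (0.44 ± 0.22), pgl-2 (0.43 ± 0.58) and mut-7 (0.36 ± 0.12) did not pass. The gene znfx-1 passed after quantile normalization (adjusted p = 0.038) and without prep 1 (0.046), and pgl-2 without prep 2 (0.048). Adjusted over the list alone, 31, 12 and 25 members of these lists were higher. With preps 1, 2 and 3 left out in turn, 23, 22 and 20 germ granule genes were higher.

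The meiosis, cell cycle and proteasome lists were also higher in camera with the preset correlation (adjusted p = 4.2e-13, 9.9e-18 and 7.4e-11), with adjusted p = 0.58 with an estimated correlation for each. Of 33 meiosis genes, 29 were higher (31 adjusted over the list alone), with a mean of 0.88 ± 0.23. Without preps 1, 2 and 3 in turn, 28, 27 and 24 were higher. The axis protein gene htp-3 stood at 1.48 ± 0.38 and brd-1, the worm counterpart of BARD1, at 1.44 ± 0.68, whereas him-8 (0.49 ± 0.39), lab-1 (0.44 ± 0.08), syp-3 (0.36 ± 0.17) and him-5 (0.25 ± 0.43) did not pass. After quantile normalization lab-1 (adjusted p = 0.031) and him-8 (0.039) passed, and lab-1 also after scaling (0.044). Cell cycle and mitosis genes were higher for 45 of 55 members (46 adjusted over the list alone), with a mean of 0.98 ± 0.25. The B-type cyclin gene cyb-3 (1.93 ± 0.61) and the replicative helicase gene mcm-2 (1.89 ± 0.61) led them, and bir-1 (0.03 ± 0.23) and cdk-2 (−0.15 ± 0.17) did not pass. Of 31 proteasome genes 25 were higher (28 adjusted over the list alone) at a mean of 0.82 ± 0.39, from rpn-1 (1.6 ± 0.38) and rpn-2 (1.32 ± 0.20) down to pbs-4 (0.39 ± 0.30) and pas-4 (0.36 ± 0.42), which did not pass. Leaving out preps 1, 2 and 3 in turn left 20, 26 and 18 proteasome genes higher, with means of 0.616, 1.008 and 0.828.

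The major sperm protein list and the sperm function list were lower in camera with the preset correlation (adjusted p = 2.2e-12 and 0.028), with adjusted p = 0.58 with an estimated correlation for both. Of 41 genes of the major sperm protein family and its relatives, 31 were lower and 10 did not pass, with a list mean of −1.2 ± 0.43. Adjusted over the list alone, 32 were lower and 2 higher. The parts of the list differed in their counts: 29 of 30 msp genes were lower (mean −1.57 ± 0.54), against 2 of 11 of the related ssp genes (mean −0.21 ± 0.13), which did not pass as a group (adjusted p = 0.302). Without prep 1 or prep 2, 1 ssp gene was lower (mean −0.135 without prep 2), and after quantile normalization 3 were lower and 1 higher. This split was chosen after the values were seen, and the difference between the parts was not tested. The lowest were msp-59 (−2.60 ± 0.79) and msp-51 (−2.50 ± 0.51). The highest was msp-38 (0.47 ± 0.30), which did not pass, except as higher after quantile normalization (adjusted p = 0.035 in limma). The gene ssp-37 (0.29 ± 0.16) did not pass, except for 1 of its 2 probes after quantile normalization (adjusted p = 0.041). These probes can bind more than the named member of the family. Genes with other functions in sperm were mixed: of 31, 10 were lower and 3 higher, the same counts as adjusted over the list alone, and the mean was −0.28 ± 0.11. The gene sss-1 stood at −1.94 ± 0.33 and nspd-3 at −1.1 ± 0.30, whereas spe-39, which also acts in vesicle traffic outside sperm, stood at 1.13 ± 0.60. The other higher ones were spe-44 (0.84 ± 0.56), lost without prep 1 (adjusted p = 0.055), and spe-12 (0.58 ± 0.39), lost without prep 2 or prep 3 (0.373 and 0.055). For sperm function the adjusted p of camera was 0.056 without prep 1 (mean −0.22), 0.13 without prep 3 (mean −0.33) and 0.055 with 1 row per gene, where the list mean stayed at −0.28 ± 0.11 and that of the other rows moved from −0.026 to −0.052.

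The cuticle collagen list and the moulting and apical matrix list were lower in camera with the preset correlation (adjusted p = 4.5e-07 and 6.1e-07), with adjusted p = 0.58 with an estimated correlation for both. Of 152 cuticle collagen genes, 72 were lower, 19 higher and 61 did not pass, and the mean was −0.67 ± 0.44. Adjusted over the list alone, 75 were lower and 19 higher. The range ran from rol-8 and col-36 at the low end to col-143 (2.28 ± 0.72) and col-101 at the high end. Of 81 moulting and apical matrix genes, 35 were lower, 2 higher and 44 did not pass, also when adjusted over the list alone, with a mean of −0.54 ± 0.12. Without prep 1, 32 of them were lower, and without prep 2 or prep 3, 24. The ground-like genes grl-20 (−2.78 ± 0.94) and grl-3 (−2.62 ± 0.30) were lowest, and the higher ones were the cuticlin gene cut-2 (1.1 ± 0.09) and nhr-23 (0.93 ± 0.52), a nuclear receptor needed for moulting.

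The lists of neuronal and nuclear hormone receptor genes were lower in camera with the preset correlation (adjusted p = 9.0e-11 and 0.00026), with adjusted p = 0.58 with an estimated correlation for both. Of 77 neuronal genes, 42 were lower and 2 higher (44 and 2 adjusted over the list alone, with 1 higher without prep 1 or prep 2), with a mean of −0.74 ± 0.14. The FMRFamide-like peptide gene flp-1 (−3.42 ± 0.44) and the synaptotagmin gene snt-4 (−2.68 ± 0.22) were lowest, and the tyrosine decarboxylase gene tdc-1, which is also expressed in the gonadal sheath, was higher (0.88 ± 0.32). The other higher one, unc-11 (0.74 ± 0.71), lost its call without prep 1 (adjusted p = 0.206) and without prep 2 (0.11), and after scaling of the arrays (0.067). Of 239 nuclear hormone receptor genes, 64 were lower and 7 higher (63 and 7 adjusted over the list alone), with a mean of −0.29 ± 0.09, and the lowest were nhr-21 (−2.19 ± 0.13) and nhr-18 (−2.16 ± 0.46). Without prep 2, 40 of them were lower and 3 higher.

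**Figure D2:**
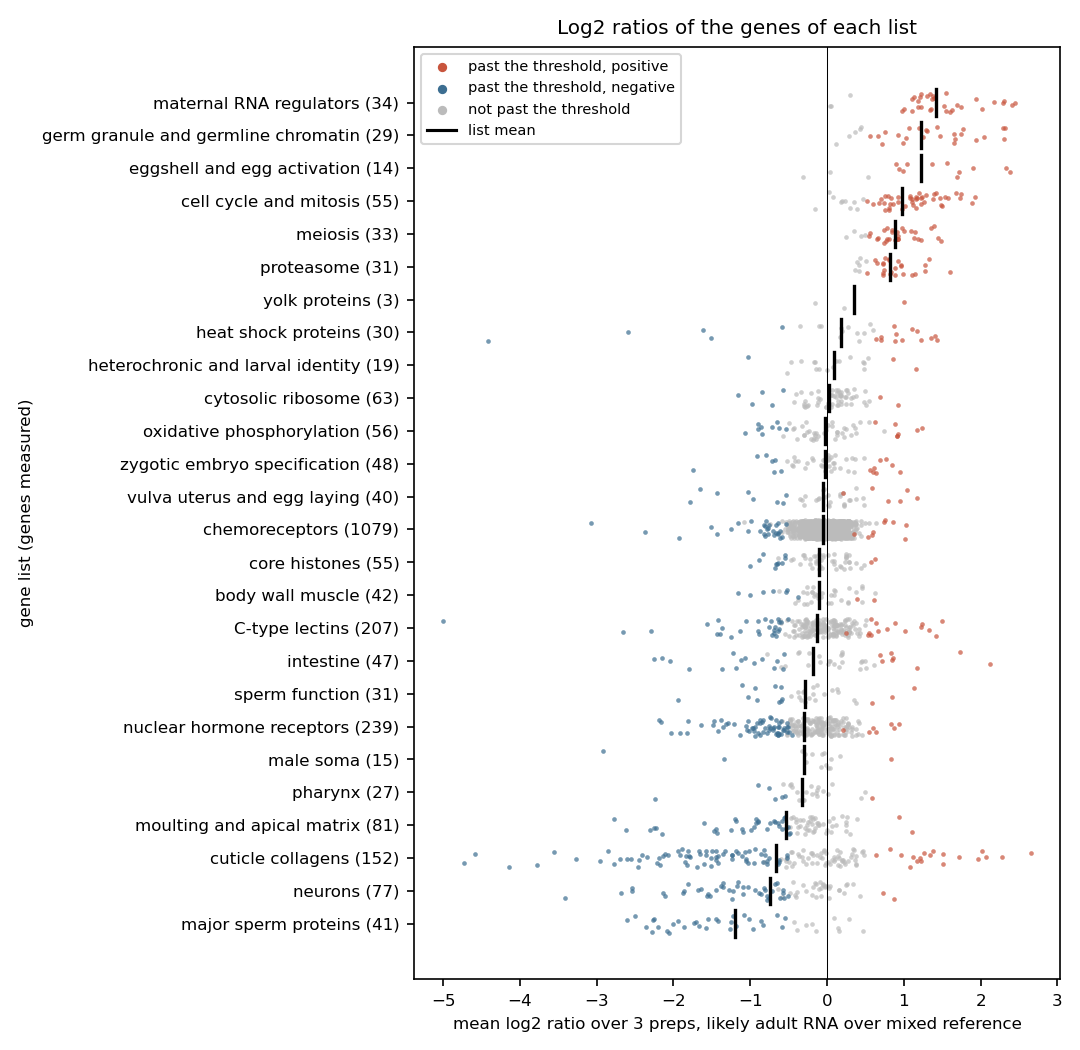
Mean log2 ratio over the 3 preps (x axis, likely adult RNA over mixed reference) of each measured gene of the 26 lists (y axis, number of genes in brackets); colour shows whether at least 1 probe of the gene passed the adjusted threshold and in which direction, and black bars are list means. The list means run from 1.41 for maternal RNA regulators to −1.2 for major sperm proteins, and the cuticle collagens hold genes at both ends.

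Heat shock protein genes went both ways. Of 30, 13 were higher and 5 lower (16 and 5 adjusted over the list alone), with a mean of 0.18 ± 0.19 and a median of 0.52. The mean was 0.084 without prep 1 and 0.275 without prep 2. Of its 9 chaperonin (cct) and DnaJ (dnj) genes, 7 were higher and 2 did not pass (mean 0.88 ± 0.33), and camera called them higher (adjusted p = 1.6e-05, and adjusted p = 0.524 with an estimated correlation). Of the 21 hsp genes, 6 were higher, 5 lower and 10 did not pass, with a mean of −0.12 ± 0.14 and no call (adjusted p = 0.496), while camera gave up as their direction, and down without prep 3. Without prep 2 their mean was −0.049. This split was chosen after the values were seen. The chaperone genes hsp-110 (1.43 ± 0.38) and dnj-13 (1.40 ± 0.41) were highest. The small heat shock protein genes hsp-12.6 and hsp-12.3 (−2.59 ± 0.47) were lowest, and hsp-70 (−1.62 ± 0.27), hsp-16.20 (−1.51 ± 0.60) and hsp-16.21 (−0.59 ± 0.16) were lower too. The call of hsp-16.21 was lost without prep 2 (adjusted p = 0.123) and without prep 3 (0.059). For the whole list the adjusted p of camera was 0.0087, and adjusted p = 0.58 with an estimated correlation. Without prep 3 it was 0.21, with a mean of 0.18 as before.

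Of 27 pharyngeal genes, 6 were lower and 1 higher, also when adjusted over the list alone, with a mean of −0.32 ± 0.22, and 0 were higher without prep 2 or prep 3. The pharyngeal troponin C gene tnc-2 was lowest (−2.24 ± 0.34), followed by abu-12 (−0.90 ± 0.68). The higher gene, abu-14 (0.58 ± 0.18), lost its call when any of the preps was left out (adjusted p = 0.055, 0.069 and 0.088). The camera adjusted p was 0.028, with adjusted p = 0.58 with an estimated correlation, 0.115 without prep 1, where 3 genes were lower and the mean was −0.196, 0.089 without prep 3 (mean −0.38) and 0.055 with 1 row per gene (mean unchanged). After removal of a running median along the probe IDs the adjusted p was 0.063, with a mean of −0.27 ± 0.18 against −0.32 ± 0.22 before, so the call ended with most of the difference still there. Of 42 body wall muscle genes, 7 were lower and 2 higher (3 and 0 adjusted over the list alone; 7 and 1 without prep 1; 3 and 1 without prep 2), with a mean of −0.11 ± 0.02. The calsequestrin gene csq-1 (−1.16 ± 0.26) and unc-98 (−1.01 ± 0.16) were lowest. The higher ones were unc-52 (0.61 ± 0.50), whose call was lost without prep 1 (adjusted p = 0.178), without prep 2 (0.157), after scaling (0.054) and with probes on at least 2 arrays (0.051), and pat-12 (0.39 ± 0.28, 1 of its 2 probes past the threshold), whose call was lost without prep 1 (0.162), without prep 3 (0.083) and with probes on at least 2 arrays (0.052). The list did not pass (adjusted p = 0.46).

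Intestinal genes went both ways, with 15 of 47 lower and 8 higher (16 and 11 adjusted over the list alone) and a mean of −0.19 ± 0.33. The acyl-CoA dehydrogenase gene acdh-1 (2.13 ± 0.91) and the P-glycoprotein gene pgp-1 (1.73 ± 0.81) were highest, and the metallothionein gene mtl-1 (−2.25 ± 0.20) and the lysozyme gene lys-3 (−2.15 ± 0.98) were lowest. The mean was −0.349 without prep 1 and −0.019 without prep 2. The list did not pass in camera (adjusted p = 0.468 with the preset correlation and 0.977 with an estimated correlation of 0.476). Without prep 1 it passed as lower with the preset correlation (adjusted p = 0.034), and the estimated correlation was not tried there.

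Ribosomal protein genes averaged 0.03 ± 0.46, with 2 of 63 higher and 5 lower (2 and 4 adjusted over the list alone). The list did not pass in camera (adjusted p = 0.825 with the preset correlation, and 0.977 with an estimated correlation of 0.825, the highest of the lists). Its direction depended on the prep. With the preset correlation it was called lower without prep 1 (mean −0.186, adjusted p = 0.034) and higher without prep 2 (mean 0.271, adjusted p = 0.015), where 7 members were higher and 2 lower. The estimated correlation was not tried with a prep left out. Paralogs of 2 pairs stood at both ends. The gene rpl-11.1 was higher (0.92 ± 0.51) and rpl-11.2 lower (−0.98 ± 0.39). The gene rpl-23A.1 was lower (−1.15 ± 0.43) and rpl-23A.2 higher (0.69 ± 0.32), a call that was lost without prep 3 (0.56, adjusted p = 0.143). The other lower ones, rpl-36A (−0.85 ± 0.39), rpl-38 (−0.71 ± 0.34) and rps-17 (−0.57 ± 0.37), lost their calls without prep 2 (adjusted p = 0.073, 0.129 and 0.311), and rps-17 also without prep 1 (0.075). Oxidative phosphorylation genes showed a similar spread over preps (mean −0.02 ± 0.40, −0.206 without prep 1 and 0.194 without prep 2, adjusted p = 0.908), with 7 of 56 higher and 9 lower (7 and 8 adjusted over the list alone; 10 and 3 without prep 2). The genes ucr-2.3 (1.23 ± 0.60) and asb-1 (1.17 ± 0.44), for subunits of the cytochrome bc complex and of ATP synthase, were highest, and asg-2 (−1.07 ± 0.49), for another ATP synthase subunit, was lowest.

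**Figure D3:**
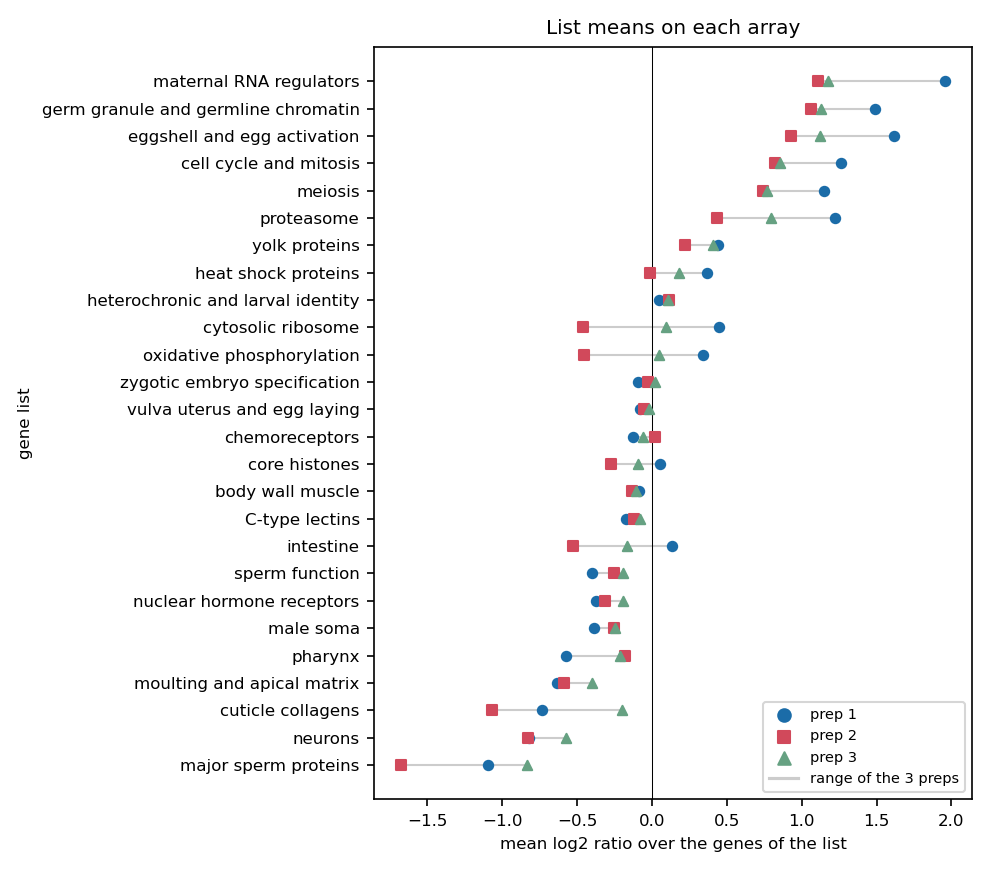
Mean log2 ratio over the genes of each list (x axis, likely adult RNA over mixed reference) on each of the 3 arrays (points), with the lists on the y axis and grey lines for the range of the 3 preps. The preps lie on the same side of 0 for the maternal, germline and meiosis lists, and the ribosomal list runs from −0.46 on prep 2 to 0.45 on prep 1.

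The remaining lists did not pass. Genes of zygotic embryo specification were higher for 8 and lower for 7 of 48 members (9 and 7 adjusted over the list alone), with adjusted p = 0.979 and a mean of −0.03 ± 0.06 against a median of 0.01. Without prep 1, 2 were higher and 5 lower, and without prep 2, 5 were higher and 4 lower, and the mean lay between −0.0017 (without prep 1) and −0.060 (without prep 3). The SKN-1-dependent gene sdz-28 was highest (0.96 ± 0.42) and the trehalose-6-phosphate synthase gene tps-1 lowest (−1.75 ± 0.44). The list thus also holds genes with other functions, and the value of tps-1, an enzyme gene, does not speak for embryo specification. The core histone list held all measured genes with the symbol his, among them his-24, a linker histone gene. Of these 55 histone genes, 10 were lower and 2 higher (10 and 1 adjusted over the list alone). Their mean was −0.11 ± 0.16 (camera adjusted p = 0.41), and his-10 was lowest (−1.0 ± 0.27). Without prep 1, 12 were lower and 1 higher (mean −0.185), without prep 2, 3 and 2 (mean −0.022), and without prep 3, 5 and 0. The higher ones were his-47 (0.63 ± 0.29), lost without prep 1 or prep 3 (adjusted p = 0.061 and 0.068), and his-24 (0.57 ± 0.35), lost without prep 2 or prep 3 (0.084 and 0.375). Of 15 male somatic genes, 1 was higher and 2 lower, also when adjusted over the list alone (mean −0.30 ± 0.08, adjusted p = 0.41): egl-46 (0.83 ± 0.28), nlp-8 (−2.92 ± 0.27) and the protease inhibitor gene swm-1 (−1.35 ± 0.41). Of 19 heterochronic genes, 2 were higher and 1 lower, also when adjusted over the list alone (mean 0.09 ± 0.04, 0.166 after removal of the running median, adjusted p = 0.712), and 4 and 3 without prep 1. The Argonaute gene alg-2 stood at 1.15 ± 0.37, nhl-2 at 0.86 ± 0.69 (adjusted p = 0.065 without prep 1) and lin-29 at −1.03 ± 0.70.

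Genes of the vulva, uterus and egg laying were higher for 6 and lower for 8 of 40 members, also when adjusted over the list alone (adjusted p = 0.979). Without prep 2, 4 were higher and 5 lower. Their mean was −0.05 ± 0.03, while their median was 0.02 and camera's direction was up. The netrin receptor gene unc-40 (1.17 ± 0.22) and the type IV collagen gene emb-9 (1.05 ± 0.29) were highest, and the Wnt gene egl-20 (−1.78 ± 0.25) and the prolyl hydroxylase gene egl-9 (−1.66 ± 0.35) lowest. Of 1079 chemoreceptor genes, 30 were lower and 9 higher (7 and 1 adjusted over the list alone), at a mean of −0.06 ± 0.07 (adjusted p = 0.552), and 19 were lower without prep 1. Their mean was −0.022 without prep 1 and −0.095 without prep 2. The lowest was srx-95 at −3.08 ± 0.69. Of the C-type lectin genes, 28 were lower, 15 higher and the rest did not pass (22 and 12 adjusted over the list alone), with a mean of −0.13 ± 0.05 (adjusted p = 0.316). The highest was clec-186 at 1.5 ± 0.13.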

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

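The removal of a running median and the addition of probes with several genes were chosen after the data were seen. Under the other centrings and scalings, probes on at least 2 arrays, robust eBayes, limited ratios and the running median, between 6185 and 7466 probes passed, and 88.4% to 100% of the 6302 calls were kept, none with the opposite sign. The test against a log2 ratio of 0.5 left 1858 probes, 800 higher and 1058 lower, as its construction requires. Leaving out a prep gave 5138 to 5394 probes and kept 76.5% to 81.0% of the calls. Probes higher by at least 2-fold numbered 710 to 1414, the lowest without prep 1. Turning the sign of 1 array gave 0 calls at most, against 6302 with the real signs, which is 1 of 4 sign patterns, too few for a share under 0.05.

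With a correlation estimated from the arrays, adjusted p = 0.58 for each of the 14 lists that passed with the preset 0.01. That form of camera has 2 degrees of freedom, so few lists could pass it. The estimated correlations of these lists ran from 0.034 for moulting to 0.764 for the proteasome, so the preset may also be too low for some. Leaving out each prep in turn, the adjusted p of camera ranged from 0.042 to 0.13 for sperm function, from 0.013 to 0.115 for the pharynx, from 0.014 to 0.21 for heat shock proteins, from 0.034 (lower, without prep 1) to 0.954 for the intestine, and from 0.015 (higher, without prep 2) to 0.897 for the ribosome, whose direction turned without prep 1 (0.034). With 1 row per gene it was 0.055 for sperm function (mean −0.28) and for the pharynx (mean −0.32), both means unchanged, and with the running median removed 0.063 for the pharynx (mean −0.27). The cause was not tested. Lists were not run with trimmed mean centring, robust eBayes, treat or limited ratios. In the settings run, other list results kept their direction and side of the threshold, except for the direction of lists that did not pass. The 5 list means nearest 0 also moved by over 1.5 times with the centring, scaling or running median. So did that of the heterochronic genes, from 0.088 to 0.166 with the running median removed. Of the named genes' values under alternatives, 872 kept their side of the threshold, 30 lost and 22 gained it. Adding probes with several genes (9 chemoreceptor, 2 lectin and 2 nuclear receptor probes) changed no call. Leaving such probes out was not run, since they were already out. Without intensities, dim probes cannot be told from bright ones.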

Other observations

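The scan of gene families, that of numbered pairs, the genes named from both, and the tests of neighbouring genes, gain, dye bias and growth were chosen after the results were seen. Among 187 families of at least 8 genes sharing a symbol, camera with the preset correlation called 61, 24 higher and 37 lower. With an estimated correlation, and so with 2 degrees of freedom, it called 0 (lowest adjusted p = 0.666), and 0 had an unadjusted p under 0.05. Nuclear pore genes were the first of the higher families outside the fixed lists: 18 of 21 npp genes were higher (mean 1.05 ± 0.26, SD over 3 preps, adjusted p = 7.2e-10), up to 2.15 ± 0.66 for npp-10. Of 11 splicing genes named prp, 8 were higher (0.75 ± 0.13, adjusted p = 0.00036). The same held for 7 of 8 ubiquitin-specific protease genes (usp, 0.86 ± 0.35, adjusted p = 0.0012) and 10 of 19 translation initiation genes (eif, 0.52 ± 0.26, adjusted p = 0.0012). Of 53 neuropeptide-like genes (nlp), 37 were lower (−1.16 ± 0.25, adjusted p = 3.9e-15). So were 24 of 46 transthyretin-related genes (ttr, −0.72 ± 0.23, adjusted p = 3.7e-07), with ttr-27 at −3.41 ± 0.36 and ttr-50 higher at 1.15 ± 0.26. Insulin-like genes were lower for 10 of 22 (ins, −0.58 ± 0.16, adjusted p = 0.00075) and pals genes for 15 of 23 (−0.73 ± 0.24, adjusted p = 0.00075). These 8 families kept their direction and call under each scaling and without each prep.

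Of 81 pairs of genes that share a name and carry its first and second number, 2 had a higher and a lower member (2.47%, against 5.74% expected from independent members). Both pairs encode ribosomal proteins, but other ribosomal pairs did not part. The genes rpl-37.1 and rpl-37.2 stood at −0.01 and 0.09, and rplp-2.1 and rplp-2.2 at 0.06 and 0.07, none past the threshold. The ratio of rpl-11.1 exceeded that of rpl-11.2 by 1.90 ± 0.15 on the log2 scale, and that of rpl-23A.1 differed from that of rpl-23A.2 by −1.84 ± 0.15, with the same sign on all 3 arrays. The call of rpl-23A.2 itself was lost without prep 3 (0.56, adjusted p = 0.143). In 12 pairs the members differed by at least 1 on the log2 scale with the same sign on all 3 arrays. The values of rif-1.1 and rif-1.2 were 1.49 and −0.16.

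Each array's deviations from the probe mean were correlated between consecutive probe IDs, with r across probes, which are not independent replicates, of 0.321, 0.185 and 0.183 on preps 1, 2 and 3, where 100 shuffles of the IDs reached 0.022 at most. Neighbouring genes with related expression as the source are excluded by the value for consecutive IDs whose genes lie more than 10 genes apart, which was 0.327 on prep 1 (95% interval over pairs treated as independent, 0.312 to 0.343). These are 99.6% of the consecutive pairs whose genes are placed, so the value had to lie near that of all pairs and cannot speak for position on the array. Genes next to each other in the genome with IDs more than 100 apart, which are other pairs, gave 0.159 (0.140 to 0.179) on prep 1. On preps 2 and 3 they gave 0.167 and 0.099, against 0.186 and 0.176 for consecutive IDs with genes more than 10 genes apart. The neighbours on prep 1 met the condition first set for related expression, and the condition on distant genes was added later. Position stays open, since the layout of the array was not used here.

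Prep 2 lay below both other preps for several lists: for ribosomal genes prep 1 exceeded it by 0.914 ± 0.053 on the log2 scale (SE over genes, 63 of 63 genes) and prep 3 by 0.556 ± 0.034 (61 of 63), and for oxidative phosphorylation these differences were 0.800 and 0.502, for the proteasome 0.784 and 0.359, and for the intestine 0.660 and 0.357. A larger gain on prep 1 as the whole cause is excluded for the ribosomal genes on these arrays by the difference of 0.796 ± 0.041 that remained after scaling the arrays. After scaling, the difference between preps 1 and 2 was 0.717 for oxidative phosphorylation, 0.652 for the intestine and 0.350 for the proteasome. The SE treats genes as independent and holds no spread between arrays of a prep. A dye bias that grows with abundance was not excluded. Major sperm proteins and collagens, low in the adults but from abundant transcripts, also lay above prep 2. They did so by 0.578 ± 0.079 and 0.338 ± 0.059 on prep 1 (0.836 and 0.871 on prep 3), and chemoreceptors did not (−0.146 ± 0.015 and −0.082). Abundance was assumed here and not measured, and body wall muscle (0.047 ± 0.12) and the pharynx (−0.398 ± 0.095) did not follow. For the 3 yolk protein genes the difference was 0.216 ± 0.293 on prep 1 and 0.181 ± 0.027 on prep 3. Sperm proteins and collagens exceeded prep 2 by more on prep 3 than on prep 1, and ribosomal genes by more on prep 1. The reason for these unlike orders was not tested. A difference in growth or age between the worm preps stays open, since 1 array per prep cannot separate prep from array.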
